A study of Mus musculus with 2 samples.

How the data were processed

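Gene expression was measured in B cells positive for surface IgM and IgD that were sorted by flow cytometry from mouse spleen. The series was designed to set wild-type cells against cells lacking serum response factor (SRF), a transcription factor that binds the promoters of immediate early and cytoskeletal genes. The samples used here are 2 arrays of the wild-type group, and arrays of SRF-deficient cells were not analysed here. The comparison of genotypes was therefore not made, and the comparisons below are between the 2 wild-type samples and against an expression floor. Both samples were placed in the wild-type group by their label for genetic modification. Replicate 1 and replicate 2 are names given in accession order and carry no order in time. The labels do not say whether the samples came from separate mice or separate sorts. Sex-linked genes, given below, differed as between female and male cells.

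Per the labels' protocols, biotinylated cRNA was prepared from 6 µg of total RNA by the array maker's standard procedure. The deposited values are signal intensities on a linear scale, computed with MAS5 per the submitters' processing notes, which give no version or parameters. MAS5 condenses the perfect-match and mismatch probes of a probe set to 1 signal and multiplies each array by 1 factor. The mean signal after trimming 2% at each end was 150.0 on replicate 1 and 150.1 on replicate 2, so both deposited columns had been scaled to a common target. A dim array gets a larger factor, which also multiplies its background. No detection calls were used here. No counts lie behind the values, and the number of arrays limits the precision.

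The table held 22690 probe sets, of which 64 were control probe sets and were left out of all gene results. Genes were named from the platform annotation supplied with the series. Of the 22626 other probe sets, 20380 named 1 gene, 691 named several and 1555 were unnamed here. No symbol changed when they were looked up by Entrez identifier in the RefSeq annotation of GRCm38.p6. Only probe sets naming 1 gene were used for genes, which gave 12393 genes. A gene was represented by its probe set with the highest mean log2 signal over both arrays. Signals of different probe sets were not compared as amounts of RNA, because probes differ in affinity.

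The floor of an array was the 90th percentile of the signals of 78 probe sets of 54 genes restricted to other organs, such as liver, brain, testis or lens. It was 167 on replicate 1 and 87.1 on replicate 2. By construction about 10% of these probe sets lie above it on each array. A gene counted as above the floor on both arrays if at least 1 of its probe sets was. Differences are log2 signals of replicate 2 minus replicate 1, without further normalization. The spread is the pooled standard deviation of log2 signal over probe sets above the floor on both arrays.

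In all, 29 gene lists were fixed before the data were examined, as were the floor, the alternatives and the rule for named genes. They covered B cell identity and receptor signalling, antigen presentation by MHC class II, immunoglobulin chains, 6 kinds of B-lineage cell, 8 other cell types, SRF and its cofactors, immediate early and cytoskeletal SRF targets, homing and adhesion, heat shock and stress, proliferation, interferon response, NF-kB targets and activation, ribosomal proteins, oxidative phosphorylation, sex-linked genes and the genes restricted to other organs. Srf, Icam1, Itgb1, Ccr6, Ccr7, Cxcr5 and S1pr1 stand in more than 1 list. The pattern that collected immunoglobulin names also took in Ighmbp2, which encodes a helicase. For each list with at least 5 genes above the floor, the median difference was placed among the medians of 10000 random lists of the same size, matched gene by gene on mean signal among 100 neighbours. The percentile describes these 2 arrays and is not a test across samples. With 2 samples of 1 group no p-value was computed.

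The genes named below are every member of the SRF list, up to 4 members of each other list with the highest mean signal above the floor (where none was above it on both arrays, the highest), list members over 2-fold apart between the arrays, and the 10 genes with the largest difference in each direction among genes above the floor on both. Where a list had many such members, examples are named, and a few more genes, chosen after their values were seen, are marked as such. All measured sex-linked genes are named too, a choice also made later. Among the 903 genes with 2 probe sets above the floor on both arrays, the one with the highest mean was over 2-fold higher on replicate 2 in 267 genes and on replicate 1 in 53. The alternatives were a 95th-percentile floor, a floor at the array median, no floor, quantile normalization, centring on the array median, log2(signal + 32), leaving out probe sets ending in _x_at, the mean over a gene's probe sets, the mean over those above the floor on both arrays (added after seeing the data), and leaving out each array. On simulated arrays of 3777 genes with the observed spread, 99.0% of genes changed 8-fold were over 2-fold apart, as were 28.6% of unchanged genes. Of 100 simulated lists of 10 unchanged genes, 4 fell outside the central 95% of random lists, and all 100 lists raised 8-fold did. A raise of 8-fold exceeds the largest list shift seen below, 5.09-fold. The simulation therefore does not show whether smaller shifts would be found. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.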

Results

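Splenic B cells that carry both IgM and IgD on their surface comprise mainly mature recirculating cells. Their transcriptome was profiled on 2 wild-type arrays, 1 per sample, each with 22626 gene probe sets. The median signal was 103 on replicate 1 and 66.6 on replicate 2, and 7184 and 9541 probe sets lay above the respective floors. On both arrays 5659 probe sets were above the floor, which corresponded to 3828 of 12393 genes. The pooled SD of log2 signal between the samples was 0.66 over these probe sets, or 1.58-fold, and with 1 group no difference could be tested against it.

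**Figure D1:**
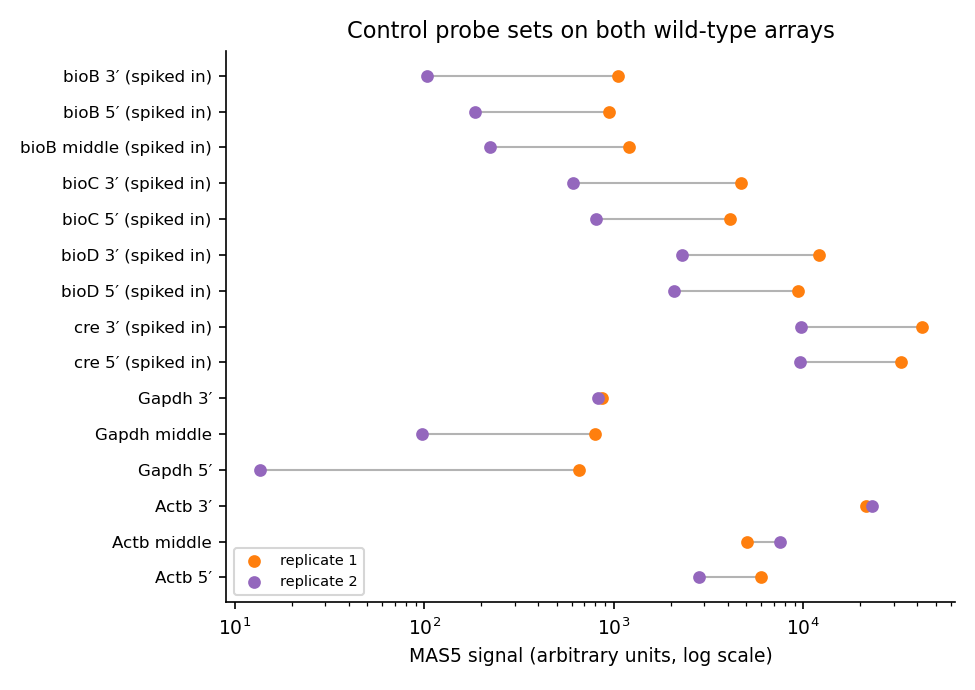
Signals of control probe sets on both wild-type arrays, on a logarithmic axis in arbitrary MAS5 units, with 1 point per array joined by a line. The spiked-in bacterial and phage transcripts are higher on replicate 1, and the 5′ probe sets of Gapdh and Actb are lower on replicate 2 while their 3′ probe sets nearly coincide.

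The wild-type cells carried the B cell programme on both arrays. Of 18 measured genes of B cell identity and receptor signalling, 17 were above the floor on both. Cd22, an inhibitory coreceptor, had a signal of 4807 ± 699 (SD, n = 2). Ms4a1, which encodes CD20, had a signal of 4870 ± 2088 (SD, n = 2). Cd79b, which encodes a signalling chain of the B cell receptor, reached 2893 ± 334 and Ly86, a partner of the receptor RP105, 2338 ± 372 (SD, n = 2). The other was Pax5, a transcription factor of B cell commitment, named after its values were seen, with signals of 21.5 and 15.6. Of the 17 genes, 13 lay within 2-fold between the arrays by the probe set used. Cd22 was among them, but its second probe set, also above the floor on both, gave 889 on replicate 1 and 274 on replicate 2. Syk, a kinase downstream of the receptor, was 3.26-fold higher on replicate 2, and Ebf1, a B lineage transcription factor, 3.33-fold, each by its brightest probe set. The mean log2 difference over the Syk probe sets above the floor was 1.12, against 1.70, and the other probe sets of Ebf1 gave 296 and 414, and 218 and 374, on replicates 1 and 2. Cd79a, which encodes the other signalling chain of the receptor, was 15.3-fold higher on replicate 1 by its only probe set, with 2931 against 192. Cd37 was 2.86-fold higher on replicate 2 by the probe set used, but its other probe set was lower there, with 307 against 1528 on replicate 1.

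Genes of antigen presentation by MHC class II were above the floor on both arrays in 8 of 9 cases. The class II chain genes H2-Aa and H2-Eb1 gave 12481 ± 3966 and 4850 ± 394, the invariant chain gene Cd74 gave 11567 ± 5862, and the cathepsin gene Ctss 4105 ± 1121 (SD, n = 2). By the probe set used, over 2-fold differences were seen for Cd74, Ciita, the class II transactivator, and H2-DMa. Cd74 and Ciita were 2.12-fold and 2.17-fold higher on replicate 1, and H2-DMa 2.47-fold higher on replicate 2. H2-Aa lay within 2-fold by the probe set used. Its second probe set, also above the floor on both arrays, gave 1771 on replicate 1 and 429 on replicate 2. H2-DMb2, named here after its values were seen, was above the floor on replicate 1 alone, with signals of 630.3 and 56.3. Among 21 genes matched as immunoglobulin chains, 8 were above the floor on both arrays. Ighm, the IgM heavy chain, gave 12796 ± 4012, Igkv8-30 gave 2393 ± 403 and Igk 346 ± 131 (SD, n = 2). Ighv14-2 was 2.12-fold higher on replicate 1, as was Ighmbp2, the helicase gene that the name pattern took in.

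Markers of follicular B cells, the recirculating subset, were all above the floor, 10 of 10. Klf2, a transcription factor of quiescence and trafficking, gave 4566 ± 2809, Tnfrsf13c, the receptor for BAFF, 2645 ± 1223, Ccr6 1862 ± 1425 and Foxo1 1200 ± 237 (SD, n = 2). Marginal zone markers were above the floor in 5 of 8 cases. These were Cr2, a complement receptor, at 1607 ± 943, Notch2 at 1098 ± 272, Dtx1 at 893 ± 276, Cd1d1, a presenter of lipid antigens, at 292 ± 17.6 and Hes1 at 231 ± 110 (SD, n = 2). Cr2 was 2.42-fold higher on replicate 2 and Hes1 2.01-fold higher on replicate 1. Of 4 markers of B1 cells 0 were above the floor on both arrays, and their highest, Cd5, gave 157 and 43.5. Immature B cell and precursor markers were above it in 2 of 11 cases, Cd24a at 1670 ± 140 and Vpreb3 at 280 ± 101 (SD, n = 2). For germinal centre cells it was 1 of 4, Bcl6 at 428 ± 148, and for plasma cells 2 of 6, Xbp1 at 1054 ± 686 and Irf4 at 809 ± 652 (SD, n = 2). Irf4 was 3.65-fold higher on replicate 1. Xbp1 was 2.71-fold higher on replicate 2 by its brightest probe set, while another gave 467 on replicate 1 and 245 on replicate 2, and the mean log2 difference over its probe sets was 0.19.

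Most markers of cells that the sort was to exclude were not above the floor. Over 8 cell types, 6 of 69 measured genes were above it on both arrays, or 8.70%, against 3.70% of the genes restricted to other organs (2 of 54, Prm1 at 205 ± 76.9 and Pomc at 190.4 ± 72.5) and 30.9% of all genes. The T cell list gave 2 of 13, Cd2, which mouse B cells also express, at 550.4 ± 353 and Zap70 at 372 ± 147 (SD, n = 2). Cd2 was 2.66-fold higher on replicate 1, and a second probe set of Zap70 gave 37.8 and 43.5, below the floor on both arrays. The receptor gene Cd3e, named after its values were seen, gave 31.1 and 16.1. Monocyte and macrophage markers gave 2 of 13, Csf1r at 268 ± 26.3 and Lyz2 at 235 ± 79.7, and neutrophil markers 2 of 8, Ngp at 257 ± 98.9 and S100a9 at 218 ± 17.3 (SD, n = 2). The other probe sets of Csf1r, each below the floor of 1 array, gave 209 and 15.2, and 23.2 and 96.7, on replicates 1 and 2. The counts were 0 of 9 for NK cells, 0 of 6 for erythroid cells, 0 of 5 for platelets and megakaryocytes, 0 of 7 for dendritic cells and 0 of 8 for stroma and endothelium. The highest of each were Prf1 with 129 and 133, Gata1 with 291 and 40.6, Itga2b with 161 and 102, Itgax with 148 and 109.9, and Col1a2 with 140.1 and 99.9 on replicates 1 and 2. Of the monocyte and macrophage markers, 2 were above the floor of replicate 1 and 6 above that of replicate 2. The floor of replicate 2 was lower, 87.1 against 167. Of all gene probe sets, 31.8% were above the floor on replicate 1 and 42.2% on replicate 2.

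Srf itself, the gene deleted in the other arm of the study, was above the floor in both wild-type samples. Its signal was 389 on replicate 1 and 254 on replicate 2, a mean of 322 ± 96.0 (SD, n = 2), a 1.54-fold difference. A second Srf probe set gave 91.7 and 109.9 and was above the floor on replicate 2 only. Of 7 genes for SRF and its cofactors, 4 were above the floor on both arrays. Mrtfa, an actin-regulated coactivator, gave 225 ± 79.9, and the ternary complex factors Elk4 and Elk1 gave 1452 ± 1278 and 158 ± 40.2 (SD, n = 2). Elk4 was 4.29-fold higher on replicate 2 by this probe set, while its other probe sets, below the floor on replicate 1, gave 130 and 109.8, and 119 and 93.8. Elk3, with 122 and 98.8, was above the floor on replicate 2 only. Mrtfb, with 162 and 11.4, and Myocd, the muscle coactivator, with 80.1 and 20.2, were below it on both.

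**Figure D2:**
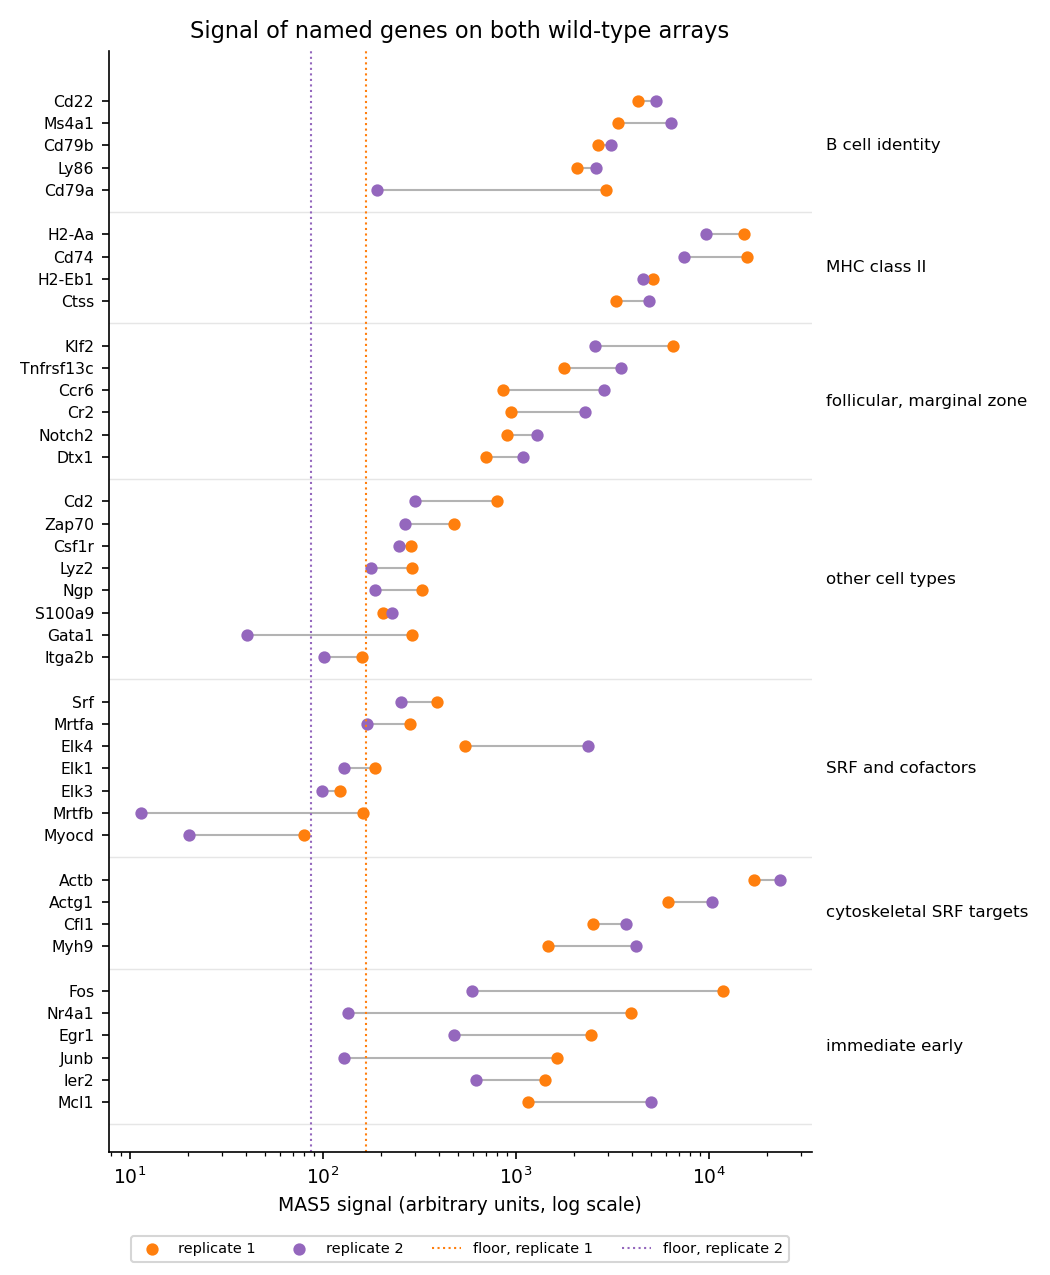
Signals of named genes on both wild-type arrays, on a logarithmic axis in arbitrary MAS5 units, with 1 point per array joined by a line and the floor of each array dotted. For Fos, Nr4a1, Egr1 and Junb the point of replicate 1 lies far to the right, while those of Cd22, Cd79b and H2-Eb1 lie close together. Each gene is shown by its brightest probe set only.

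Of 23 measured cytoskeletal targets of SRF, 15 were above the floor on both arrays. The actin genes Actb and Actg1 gave 20254 ± 4296 and 8296 ± 2996, the actin-severing Cfl1 gave 3121 ± 875 and the myosin gene Myh9 2831 ± 1934 (SD, n = 2). Another probe set of Actb, also above the floor on both arrays, gave 766 on replicate 1 and 199 on replicate 2. Another of Cfl1 gave 374 and 48.6, the latter below the floor. By the probe set used, 10 genes of the list lay within 2-fold, 3 were over 2-fold higher on replicate 2 and 2 on replicate 1. Quantile normalization left these counts unchanged, while median centring gave 7, 8 and 0. The tropomyosin genes Tpm3 and Tpm4 were 10.1-fold and 5.64-fold higher on replicate 2, and Myh9 was 2.87-fold higher there by its brightest probe set. Zyx, an adhesion protein gene, and Tagln2 were 2.61-fold and 2.01-fold higher on replicate 1. For Tpm3 another probe set above the floor gave 1084 and 1814, and the mean log2 difference over its probe sets above the floor was 2.04, against 3.34. The same mean turned Myh9 to -0.17. The list median, 0.44 on the log2 scale, lay at percentile 69.9 of random lists, and it was 0.030 under quantile normalization and -0.026 with the mean over probe sets above the floor.

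The immediate early targets of SRF had the largest median difference of the 12 lists compared between the samples. Fos, a subunit of the AP-1 transcription factor, had a signal of 11856 on replicate 1 and 593 on replicate 2, with a mean of 6224 ± 7964 (SD, n = 2). Nr4a1, an orphan nuclear receptor induced by antigen receptor signalling, was 29.4-fold higher on replicate 1, with 3963 against 135. Junb was 12.7-fold higher there, with 1639 against 129, Egr1 was 5.09-fold higher, with 2443 against 480.2, and Ier2 was 2.26-fold higher, with 1418 against 626. Of 12 genes in the list 7 were above the floor on both arrays, of which 5 were over 2-fold higher on replicate 1 (4 with median centring, without Ier2) and 1 on replicate 2. The latter was Mcl1, an anti-apoptotic gene of the Bcl2 family, with 1157 against 5019 by its brightest probe set, and Srf itself lay within 2-fold. The 5 other probe sets of Mcl1 were also higher on replicate 2, by log2 differences from 0.13 to 2.55. The lowest gave 568 on replicate 1 and 620 on replicate 2. Fosb, named after its values were seen, was above the floor on replicate 1 only, with 411 and 42.9. The median difference was -2.35 on the log2 scale, below the medians of all 10000 random lists, whose central 95% ran from -0.18 to 1.31. It kept its sign under both scalings, at -2.76 after quantile normalization and -1.71 after median centring. Each of the 5 genes over 2-fold higher on replicate 1 was measured by 1 probe set. On replicate 2 the 3′ to 5′ signal ratios of 2 control mRNAs were higher, 8.15 against 3.57 for Actb and at least 9.46 against 1.31 for Gapdh, whose 5′ signal was below the floor there and was set to it. The 3′ to middle ratio was 3.07 against 4.23 for Actb and 8.46 against 1.08 for Gapdh. For 18S ribosomal RNA the 3′ to 5′ ratio was lower on replicate 2, 0.191 against 1.18.

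Several immediate early SRF targets were also among the genes with the largest differences of those above the floor on both arrays. Of these, the 10 genes highest on replicate 1 relative to replicate 2 were Nr4a1, Jun, Cd79a, Fos, Junb, Klf4, Klf6, Dusp1, Bzw2 and Zfp36. Jun, the partner of Fos in AP-1, was 22.3-fold higher, the Krüppel-like factor genes Klf4 and Klf6 11.5-fold and 9.45-fold, the phosphatase gene Dusp1 8.48-fold, and Zfp36, which encodes a destabiliser of AU-rich mRNA, 7.13-fold. On replicate 2, with a floor of 87.1, the signals were 136 for Jun, 97.3 for Klf4, 89.9 for Klf6 and 118 for Dusp1. The folds of these genes therefore divide by signals near that floor, and their size is uncertain. The other probe sets of Jun, Klf4 and Klf6, 4 in all, were each over 2-fold higher on replicate 1 too. Bzw2 was 7.66-fold higher by 1 probe set and not by its other. The corresponding 10 genes for replicate 2 were Tpm3, Elovl5, Hadh, Ammecr1l, Trim25, Camkk2, Hax1, Tnrc6a, Uqcrb and Ythdf1, by between 10.1-fold for Tpm3 and 6.78-fold for Ythdf1. Of 12 other probe sets of these genes above the floor on both arrays, 2 were over 2-fold higher on replicate 2, and 5 of the 10 genes were represented by a probe set ending in _x_at, a class that can cross-hybridize.

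**Figure D3:**
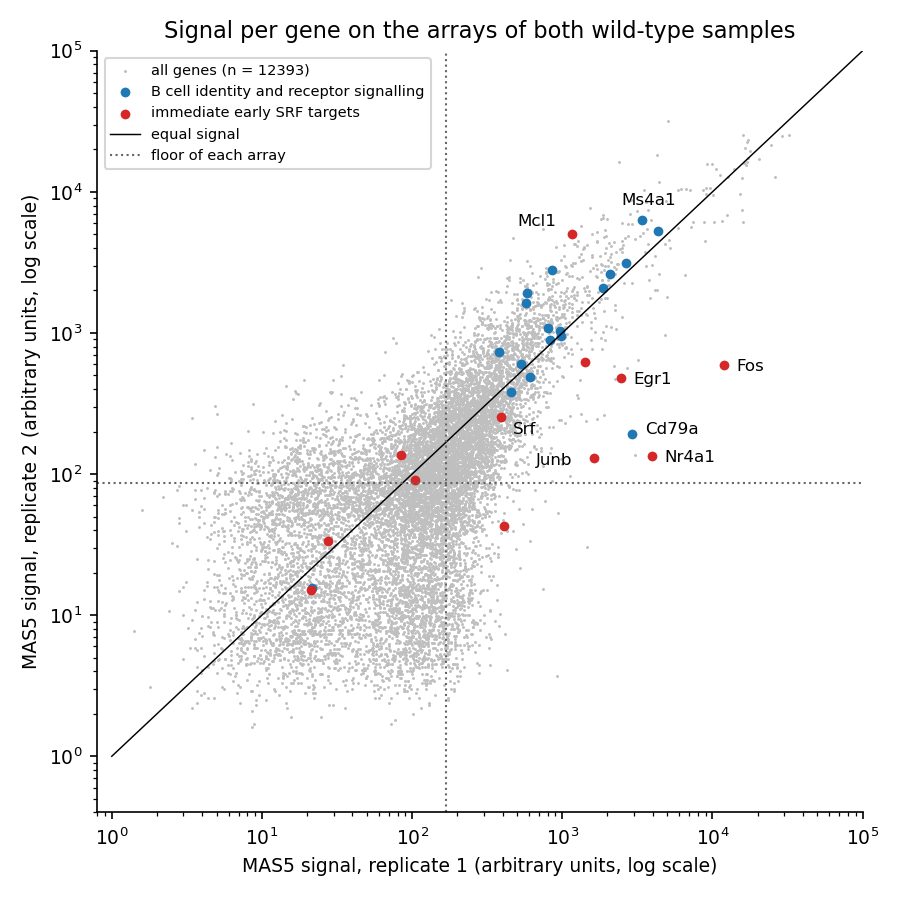
Signal of each of 12393 genes on replicate 1 (horizontal) and replicate 2 (vertical), both on logarithmic axes in arbitrary MAS5 units, with the line of equal signal and the floor of each array. Among genes of B cell identity (blue) Cd79a lies far below the line, as do Fos, Nr4a1, Junb and Egr1 (red), while Mcl1 lies above it.

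Homing and adhesion genes were above the floor in 10 of 12 cases, with differences in both directions. The chemokine receptor gene Cxcr4 was 5.03-fold higher on replicate 1, S1pr1, a receptor for egress from lymphoid organs, 5.55-fold and Ccr7 5.50-fold. Ccr6 and Cxcr5 were 3.36-fold and 2.13-fold higher on replicate 2, and Klf2 from the follicular list was 2.54-fold higher on replicate 1. The integrin gene Itgb2 gave 604 ± 94.5 (SD, n = 2). The median of the list, 0.15, lay at percentile 38.5 of random lists.

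Heat shock and stress genes were above the floor in 12 of 13 cases, with 5 over 2-fold higher on each array. The chaperone genes Hspa8, Hsph1 and Dnaja1 were 2.65-fold, 3.78-fold and 3.81-fold higher on replicate 2, each by its brightest probe set, and Hsp90aa1 gave 2093 ± 369 (SD, n = 2). Another probe set of Hspa8 gave 1337 on replicate 1 and 921 on replicate 2, and the mean log2 difference over its probe sets was 0.27. Dnajb1 was 3.62-fold higher on replicate 2 by its brightest probe set, and its other probe set gave 500.4 on replicate 1 and 18.4 on replicate 2. The inducible Hspa1a and Hspa1b were 4.15-fold and 2.81-fold higher on replicate 1, as was Ddit3 by 3.71-fold, beside Jun and Dusp1. Hspe1 gave 637 on replicate 1 and 1276 on replicate 2, and its mean over probe sets went the other way. Among NF-kB targets and activation genes, 7 of 9 were above the floor. The inhibitor gene Nfkbia gave 4362 ± 2266, with its probe sets opposed, the activation marker Cd83 gave 1899 ± 864 and Icam1 253 ± 16.2, and Rel was 3.09-fold higher on replicate 1 (SD, n = 2).

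Ribosomal protein genes were above the floor in 40 of 45 cases, and 34 of these lay within 2-fold, among them Rps29 at 26915 ± 2853, Rps28 at 23065 ± 2265, Rps3a1 at 18732 ± 2190 and Rps18 at 20593 ± 6394 (SD, n = 2). Rpl41 and Rpl10a were 4.26-fold and 2.33-fold higher on replicate 2, and Rps27, Rps24, Rpl27a and Rpl22l1 between 6.03-fold and 2.18-fold higher on replicate 1. With quantile normalization 1 ribosomal gene was over 2-fold higher on replicate 2 and 5 on replicate 1, and with median centring 10 and 1. Oxidative phosphorylation genes were above the floor in 62 of 71 cases. Of these 19 were over 2-fold higher on replicate 2, such as Uqcrb by 6.82-fold, Ndufc2 by 3.91-fold, Uqcrfs1 by 3.77-fold and Cox6b1 by 3.01-fold. Another probe set of Cox6b1 gave 1068 on replicate 1 and 902 on replicate 2, and the mean over both lowered its log2 difference from 1.59 to 0.67. With quantile normalization 10 genes of the list were over 2-fold higher on replicate 2 and 5 on replicate 1, and with median centring 36 and 2. The 3 higher on replicate 1 were Atp5l, Cox8c and Atp5mpl, by 3.40-fold, 3.21-fold and 2.60-fold. Proliferation genes were above the floor in 3 of 14 cases, Pcna at 1039 ± 151, Mcm2 at 200.2 ± 19.7 and Mcm5 at 180.1 ± 15.2 (SD, n = 2). Interferon response genes were above it in 3 of 16 cases, Rtp4 at 293 ± 53.4, Oas1a at 247 ± 62.5 and Rsad2 at 252 ± 139 (SD, n = 2), and Rsad2 was 2.29-fold higher on replicate 1.

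Of the 12 lists large enough to place among random lists, 3 lay outside the central 95%, where 0.6 would if genes differed independently. The random lists were drawn gene by gene and carry no correlation between genes of a list, and some lists share genes. The number expected by chance for real lists is therefore not known. The 3 lists were the immediate early SRF targets, the ribosomal proteins and the immunoglobulin chains. The ribosomal median was -0.05 at percentile 0.86, and the immunoglobulin median was -0.84 at percentile 1.91. The latter moved to percentile 35.4 with the mean over all probe sets, 2.70 with the mean over those above the floor and 30.2 with no floor. The 8 genes behind it included the helicase gene Ighmbp2, at -1.09. The list was not placed among random lists without that gene, so its place outside the central 95% may depend on it. Bright probe sets were on the whole higher on replicate 2, by a median of 0.51 in the brightest 10% of them, and the random lists, matched on signal, carry that shift. The sign for the ribosomal list turned to 0.59 under median centring, which adds 0.63 to every difference. Medians of B cell identity, 0.24, and MHC class II, -0.05, were inside the central range at percentiles 3.80 and 6.06, and MHC class II moved to percentile 0.87 with the mean over probe sets above the floor. Follicular genes (0.13), marginal zone genes (0.51), heat shock (0.38), NF-kB targets (-0.09) and oxidative phosphorylation (0.47) were at percentiles 17.5, 63.1, 32.6, 36.2 and 46.0. Of the 12 directions, quantile normalization kept 5, median centring 9 and the mean over probe sets above the floor 11. Quantile normalization turned those of B cell identity, follicular, marginal zone, homing, heat shock, NF-kB and oxidative phosphorylation genes, and median centring those of ribosomal, MHC class II and NF-kB genes. The mean over probe sets above the floor turned the cytoskeletal targets to -0.026. With the mean over all probe sets, which takes in those below the floor, 9 directions were kept, and heat shock was at -0.62, follicular genes at -0.26 and the cytoskeletal targets at -0.19. Heat shock lay at percentile 0.09 there, outside the central 95%, and at 16.7 with the mean over those above the floor.

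**Figure D4:**
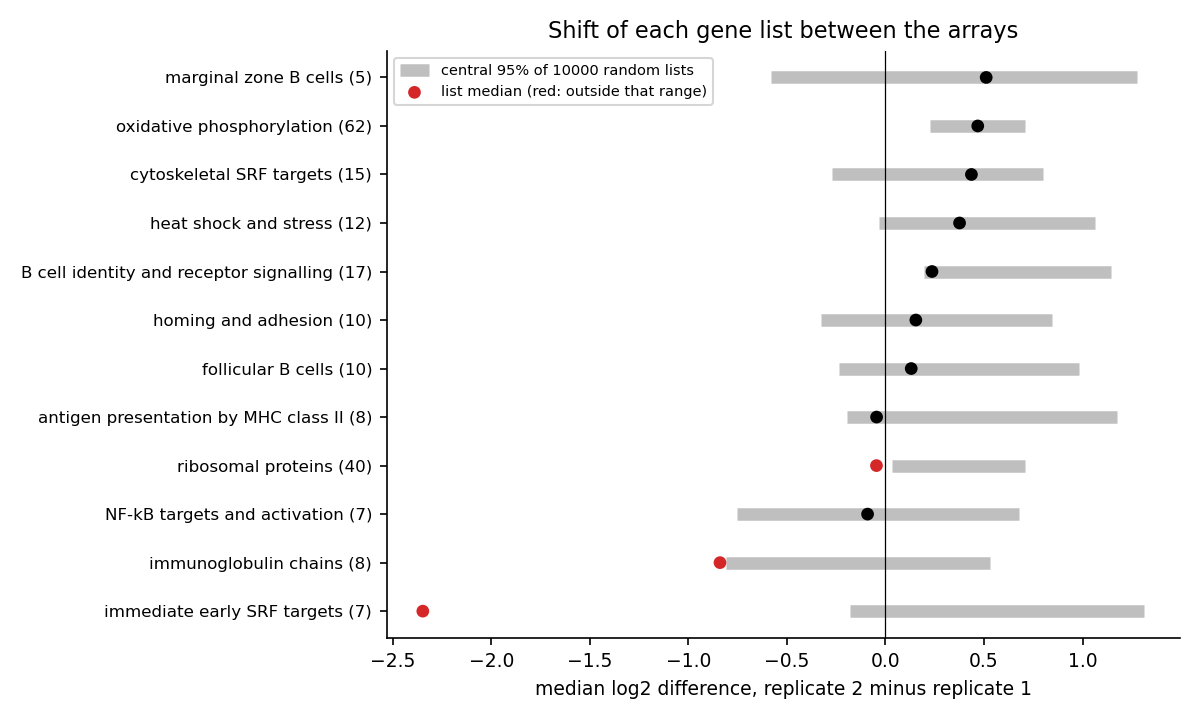
Median log2 difference between the arrays (replicate 2 minus replicate 1) of each gene list, with the number of genes in brackets and a grey bar for the central 95% of 10000 random lists matched on signal. The immediate early SRF targets lie at -2.35, outside their bar by more than any other list.

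Across all gene probe sets Pearson's r of log2 signal was 0.63 and Spearman's rho 0.62, and above the floor on both arrays they were 0.79 and 0.64. These are correlations across probe sets, which are not independent replicates. Above the floor 1586 probe sets, or 28.0%, were over 2-fold apart, 784 higher on replicate 2 and 802 on replicate 1. This split was 509 and 685 with quantile normalization and 1918 and 176 with median centring. Among 903 genes with 2 probe sets above the floor, the differences of the 2 probe sets correlated with r = 0.32 across genes and had the same sign in 59.1%.

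Sex-linked genes were measured differently on the arrays. Xist, the RNA that silences an X chromosome in females, gave 740 on replicate 1 and 15.3 on replicate 2. The Y-linked Eif2s3y gave 3.40 and 249, and Kdm5d 88.4 and 176, so both were above the floor on replicate 2 only. Uty, with 44.8 and 57.7, was below it on both. Xist was thus above the floor on replicate 1 only and 2 of 3 Y-linked genes on replicate 2 only. That is the pattern of female cells on replicate 1 and male cells on replicate 2, so by these genes the samples were not from the same mouse.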

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

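Control probe sets, which no gene result used, separated the arrays. Transcripts of Escherichia coli and phage origin are added to every sample in a fixed mixture before hybridization, and all 18 of their probe sets were above the floor on both arrays. Their median log2 difference was -2.37, so they were 5.17-fold higher on replicate 1, with a range from 3.39-fold to 13.2-fold. The probe sets of 18S ribosomal RNA went the other way by unequal amounts, with log2 differences of 0.43 for the 3′, 2.86 for the middle and 3.06 for the 5′ probe set. Both were singled out because they are signals outside the main measurement that differ between samples of 1 group.

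The wide differences between 2 arrays of 1 group are the first pattern weighed, and the test of its 5′ explanation was chosen after the ratio was seen. Noise of dim probe sets does not account for all of it, since 33.0% of the brightest 10% of probe sets were also over 2-fold apart. A loss of the 5′ part of transcripts in replicate 2 stays open. The log2 ratio of 3′ to 5′ signal was higher there by at least 2.85 for Gapdh and by 1.19 for Actb. That of 3′ to middle signal was higher for Gapdh, by 2.97, but not for Actb, at -0.46. The 3′ to 5′ change of 18S ribosomal RNA was -2.63, but this RNA is not an mRNA and was not part of the test. Errors of single probe sets stay open, since the correlation of 0.32 between probe sets of 1 gene is neither near 0 nor high. No biological explanation was tested. The sex-linked genes differed as between female and male cells, so differences of sex or of animal cannot be told apart from those of the arrays.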

How the results depend on the processing

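The immediate early shift kept its direction and stayed below the 2.5th percentile of random lists under quantile normalization, log2(signal + 32), a floor at the array median and no floor. Both means over probe sets and the 95th-percentile floor left its median at -2.35, and median centring adds a constant, which moves no percentile. It was -2.76 with quantile normalization, -1.71 with median centring, -1.76 with a floor at the array median and -0.90 with no floor. The shift of cytoskeletal targets (main 0.44) was 0.030, 1.07, 0.027 and -0.024 in the same order, -0.19 with the mean over all probe sets and -0.026 with the mean over those above the floor. That of B cell identity (main 0.24) was -0.27 with quantile normalization and 0.87 with median centring. The ribosomal shift reversed to 0.59 with median centring, which adds 0.63 to every difference. The pooled SD (main 0.66) was 0.60 with quantile normalization, 0.79 with median centring, 0.60 with log2(signal + 32) and 1.35 with no floor. The share of probe sets over 2-fold apart (main 28.0%) was 21.1%, 37.0%, 22.2% and 53.8% in that order, the last being 12171 probe sets. Pearson's r (main 0.63) was 0.74 with log2(signal + 32) and 0.79 above the floor, and r between probe sets of 1 gene (main 0.32) was 0.24 with quantile normalization. Leaving out replicate 1 or 2 gave 9541 or 7184 probe sets above the floor against 5659 on both, as a floor passed once must. With the mean over all probe sets, which takes in those below the floor, 35 of 85 named genes over 2-fold apart could not move, having 1 probe set. Of the other 50, 14 stayed within 1 pooled SD of their difference, 28 moved by more in the same direction and 8 reversed: Atp5a1 to -0.093, Cd37 to -0.40, Dnajb1 to -1.45, Hspe1 to -0.036, Myh9 to -1.26, Nfkbia to -0.22, Tagln2 to 0.76 and Zyx to 0.65. Of these, Dnajb1, Tagln2 and Zyx rest on a probe set below a floor. With the mean over probe sets above the floor, 34 genes could move, of which 12 stayed, 17 moved and 5 reversed, with Myh9 at -0.17 and Atp5a1, Cd37, Hspe1 and Nfkbia as before. Quantile normalization, median centring and log2(signal + 32) reversed none of the 85, but left 66, 68 and 78 over 2-fold apart. The share and these single-gene alternatives were added after seeing the data. The causes were not tested. No paired analysis was possible because there is 1 group. Signal over background limits the dim genes, since the floor of 167 on replicate 1 was higher than that of 87.1 on replicate 2.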

Other observations

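Atf3, a stress-induced transcription factor of the heat shock and stress list named after its values were seen, gave 258 on replicate 1 and 8.70 on replicate 2, where it was below the floor. The receptors Cxcr4, S1pr1 and Ccr7 and the costimulatory gene Cd83 were also higher on replicate 1, by 5.03-fold, 5.55-fold, 5.50-fold and 1.95-fold, while Ccr6 and Cxcr5 of the same homing list were higher on replicate 2, by 3.36-fold and 2.13-fold.

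The immediate early pattern is the second one weighed; the tests of single probe sets and of 5′ loss were chosen after the result was seen. Array scaling does not explain the place of the list relative to other genes. Its median was -2.76 after quantile normalization, still below the 2.5th percentile of random lists. Quantile normalization gives both arrays the same distribution, so it cannot test a level shared by all genes. The spiked-in transcripts were also higher on replicate 1, with a median log2 difference of -2.37. The test of faulty single probe sets was first written for all genes of the list and found 0 of 5 other probe sets over 2-fold lower on replicate 2, but all 5 belong to Mcl1, which is higher there, so it was narrowed afterwards to the 6 lower genes, which have 0 other probe sets above the floor of replicate 1 and leave faulty probe sets open. For Jun, Klf4 and Klf6, 4 of 4 other probe sets were over 2-fold lower on replicate 2, which argues against faulty probe sets for those genes, while the other probe set of Bzw2, below the floor on replicate 1, gave 114 there and 151 on replicate 2. A loss of 5′ sequence stays open, with the log2 3′ to 5′ ratio of Actb higher by 1.19 on replicate 2 and that of 3′ to middle not, at -0.46, because the files do not place the probes within transcripts, and no biological explanation was tested.

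The genes with the largest excess on replicate 2 are the third pattern, and its test was set before its result but after the names of the probe sets of these 10 genes had been seen. Cross-hybridizing probe sets are a candidate explanation: the 628 probe sets ending in _x_at above the floor on both arrays had a median difference of 0.43, above the central 95% of random probe sets of like signal (0.14 to 0.29). They made up 21.9% of the probe sets over 2-fold higher on replicate 2, 7.11% of those higher on replicate 1 and 11.1% of all above the floor. Where a gene's brightest probe set was over 2-fold higher on replicate 2, a second one was too in 48 of 267 genes, against 20 of 53 genes for replicate 1. The second is the dimmer one by construction, and the median difference fell from 0.51 in the brightest 10% of probe sets to 0.05 in the next 10%. That contrast can therefore arise without cross-hybridization and does not speak for it. The median of the class does not say how much of the excess of a single gene cross-hybridization would account for.

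A second probe set of Xist gave 1025 on replicate 1 and 5.70 on replicate 2, and the labels used here give no sex.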
